A study of Mus musculus with 2 samples.

How the data were processed

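The series holds 2 libraries of cells dissociated from mouse brain, and per the series' design text each pooled the cells of 3 brains, of WT mice in one and of Dmp1Cre-Mfn2flox/flox mice in the other. Per the labels' protocols, droplets were made and libraries built with the Chromium Single Cell 3' kit of 10x Genomics, version V3.1. Per the submitters' processing notes, CASAVA 1.8, Cell Ranger 3.1.0 and Seurat 2.3.4 were used; their roles and order are not given in the sources used here, nor is the genome build. The values the authors deposited are whole-number UMI counts per gene and barcode, not normalized, in a sparse matrix for each library. The deposited matrices held 30905 genes, of which 7751 barcodes and 54867423 UMIs were in the WT library and 11034 barcodes and 83237281 UMIs in the Dmp1Cre-Mfn2flox/flox (cKO-labelled) library. Each matrix was assigned to its group by the strain label of its sample. No cell type annotation was used.

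Barcodes with at least 500 UMIs, at least 300 genes and at most 20% of UMIs from mitochondrially encoded genes were kept, which left 7259 WT and 10263 cKO-labelled barcodes. Doublets were called in each library with the Scrublet method in Scanpy 1.11.5 and removed. The caller marked 491 cKO-labelled barcodes (4.78%, score threshold 0.170) and 4 WT barcodes (0.0551%, threshold 0.571). So few marked barcodes mean that the caller has not worked in the WT library, and doublets may remain there. The 17027 cells left were scaled to 10000 UMIs and log-transformed, and the 2000 most variable genes were scaled to at most 10 SD and reduced to 30 principal components. A graph of 15 neighbours was clustered by the Leiden method at resolution 1, with both libraries together and no batch correction, using Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, scikit-learn 1.9.0 and igraph 0.11.9. Figures were drawn with Matplotlib 3.10.9.

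Clusters were named from 25 marker lists fixed before the data were examined. The numerical rules for naming were set after the clusters were seen. A cluster needed at least 3 markers at 20 CPM or more and 2-fold above clusters of other lineages. Its mean marker level had to be at least 0.3 of the highest cluster. A second class of another lineage could score at most 0.7 of the first and have no more markers among the 10 leading genes. A low UMI count without a leading marker barred a name, as did a correlation with the whole library's profile of 0.93 or more. These rules left 5 of 33 clusters unnamed. UMIs were summed per class and library and divided by the class total to give counts scaled to a common total (CPM). Classes with at least 50 cells in each library were compared; oligodendrocyte precursor-like cells, with 32 and 21 cells, were not.

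With 1 library per group there are no replicates and cells are not replicates, so no test was made. Exact Poisson intervals are given for sums of counts, exact conditional binomial intervals for ratios, exact (Clopper-Pearson) binomial intervals for shares and Newcombe intervals for differences of shares, each at 95% and for counting error only. A count of 0 was set to a floor of 3 counts over the class, and the limit given for a share of 0 is that of 3 counts of the total, not the upper end of the binomial interval. A fold written as at least some value uses this floor. It leaves out counting error in the other library and is not the lower limit of the interval. To compare shares of cells with a UMI, each cell was thinned to 1000 UMIs, and shallower cells were left out. For 32 gene lists fixed before the data were examined, the median log2 ratio was taken over members with at least 20 UMIs over both libraries in a class, with an interval from 1000 Poisson redraws and its percentile among 10000 random lists drawn from the 100 genes nearest in level to each member. A list needed 3 measured members; 31 lists had them in at least 1 class, and the list of SIBLING genes, the family of Dmp1, did not. A percentile describes these libraries and is no p-value.

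List members are called higher or lower at a ratio of 1.5-fold or more, a rule of size and not a test. Up to 4 members of a list with the largest ratios were to be named, beside Mfn2 and Dmp1; Cldn5, Ocln, Tjp1, Mfsd2a, Aqp4 and Mbp were named after their values were seen. Other genes were named by a fixed rule: the library with the higher CPM needed at least 100 UMIs and 50 CPM in the class, and the class at least 10% of the gene's highest CPM in any class of that library. Mitochondrially encoded, ribosomal protein, haemoglobin and predicted genes were left out. Of the rest, the 10 largest ratios in each direction were named in astrocyte-like and endothelial-like cells, 5 in microglia-like cells and 3 in each other class. Some genes that these rules name are not reported here.

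The steps were tested on simulated counts with known answers, drawn as Poisson counts from a profile shared by both libraries. The intervals assume such counts, so their coverage in this simulation was largely set in advance. The simulation left out clumping of UMIs in cells, differences in the makeup of a class and free RNA. Its rates therefore cover counting error only and may be too favourable for these libraries. For astrocyte-like cells, over 8808 simulated genes, 88% of 100 genes raised or lowered 2-fold and 98% of 100 set at 4-fold were found at 1.5-fold or more in the right direction. Of unchanged genes, 19.7% passed 1.5-fold by counting error alone, and 3.79% of the 3058 with at least 100 UMIs did. For endothelial-like cells, over 10869 genes, the shares found were 96% and 100%, and 7.23% of unchanged genes passed. For microglia-like cells, over 11614 genes, they were 96% and 100%, and 4.80% passed. The interval held the true ratio for 96.8%, 96.1% and 95.8% of genes in these classes.

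Gene positions and transcript lengths came from GENCODE M21 on the reference build GRCm38, in which 30766 of the 30905 gene identifiers (99.6%) were found. It was not compared with the build of the submitters, which is not given in the sources used here. Alternatives listed before the data were examined were TMM factors (edgeR 4.0.16 in R 4.3.3), median-of-ratios size factors (DESeq2 1.42.0), cells weighted equally, totals without mitochondrial, ribosomal protein and haemoglobin genes, stricter filters (1000 UMIs, 500 genes, 10% mitochondrial), no filter, doublets kept, resolutions of 0.5 and 2, 50 principal components of 3000 variable genes, list filters of 100 UMIs and 1 UMI, and thinning to 2000 UMIs or none. Alternatives added after seeing the data were a common doublet threshold, shares of named clusters only, list members at 10% or more of their highest class (the free-RNA rule), and removal of a trend with transcript length and GC content. A comparison within the clusters of resolution 2 with at least 50 cells in each library, and intervals for shares in each setting and in named clusters only, were also added after seeing the data. Such clusters are formed from expression, partly of the genes compared. Dissociation, capture and sequencing differ between libraries along with genotype, and cell recovery, free RNA in droplets and depth can all move the values.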

Results

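Whole brains of 6-week-old male mice were dissociated and their cells profiled by droplet-based single-cell RNA sequencing with a 10x Genomics kit that counts unique molecular identifiers (UMIs) at the 3' ends of transcripts. The data came from 2 libraries. One was made from wild-type (WT) mice and the other from mice labelled Dmp1Cre-Mfn2flox/flox, in which a Cre recombinase driven by Dmp1 was used to delete Mfn2 in Dmp1-expressing astrocytes. Each library pooled the cells of 3 brains, so that each group had 1 library, no difference had a replicate check, and no test was made. The second library is called the cKO-labelled library. The WT library held 7751 barcodes and 54867423 UMIs, and the cKO-labelled library held 11034 barcodes and 83237281 UMIs. After filtering, 7255 and 9772 cells were kept, with medians of 5692 and 6239 UMIs and of 2078 and 2188.5 genes per cell. A median of 3.15% of UMIs came from mitochondrially encoded genes in the WT library and 4.33% in the cKO-labelled library. Clustering gave 33 clusters, of which 28 were named from marker genes, and 16 classes had at least 50 cells in each library. All intervals are 95% intervals and cover counting error only. Those of ratios and list medians count each UMI as an independent draw, so they are too narrow where UMIs lie in few cells. Ratios are those of the cKO-labelled library over the WT library.

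Mfn2 encodes mitofusin 2, a GTPase of the outer mitochondrial membrane that fuses mitochondria. In astrocyte-like cells its level did not differ between the libraries beyond counting error: 7 UMIs (18.7 CPM, counts scaled to a common total per class) were read in 61 WT cells and 39 UMIs (27.2 CPM) in 309 cKO-labelled cells, a log2 ratio of 0.54 (interval -0.64 to 1.95). In endothelial-like cells Mfn2 was at 17.4 CPM (45 UMIs) in the WT library and 29.2 CPM (136 UMIs) in the cKO-labelled library, a log2 ratio of 0.74 (0.25 to 1.26). The median over all genes there was 0.15. The makeup of this class differed: at resolution 2, cluster 17 held 59.3% of its WT and 2.44% of its cKO-labelled cells, and cluster 7 held 8.39% and 45.4%. Within these endothelial clusters Mfn2 was not compared. In choroid plexus epithelial-like cells Mfn2 was at 42.0 and 27.5 CPM, a log2 ratio of -0.61 (-0.94 to -0.27). Cluster 32 of this class, with a median of 32931 UMIs, held 4.29% of its WT and 12.6% of its cKO-labelled cells. Mfn2 was not compared within the clusters of this class. In 14 of the 16 compared classes, astrocyte-like cells included, the interval of the ratio held 0. The log2 ratios of Mfn2 were 1.17 in B cell-like, 0.78 in neutrophil-like, 0.46 in border macrophage-like, 0.21 in microglia-like, 0.19 in neural stem or progenitor-like, -0.03 in mural-like and -0.13 in neuron-like cells. They were -0.16 in oligodendrocyte-like, -0.34 in fibroblast-like, -0.44 in neuroblast-like, -0.47 in ependymal-like, -0.64 in T or NK cell-like and -0.79 in monocyte or dendritic cell-like cells. Mfn2 (ENSMUSG00000029020) lies on chromosome 4 from 147873599 to 147904704 on the minus strand of the reference build GRCm38. The labels do not say which part of the gene is flanked by the recombination sites, and 3' reads can come from outside the deleted part, so these values check neither the deletion nor the labels. With so few UMIs of Mfn2 in astrocyte-like cells a moderate loss was not detectable, and the log2 ratio was -0.69 when cells were weighted equally and 2.07 with stricter filters on cells.

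Among astrocyte-like cells, Dmp1, which encodes dentin matrix protein 1 and drives the Cre recombinase, was read only in those of the cKO-labelled library. No UMI of Dmp1 was read in the 61 WT cells, and 38 UMIs (26.5 CPM) were read in 28 of the 309 cKO-labelled cells. Against a floor of 3 counts over the class this was 3.3-fold higher, and the interval of the log2 ratio began at 1.36. After each cell was thinned to 1000 UMIs, 0 of 56 WT astrocyte-like cells had a Dmp1 UMI, which allows a share of up to 5.36%, against 8 of 284 cKO-labelled cells (2.82%, 1.22 to 5.47%), so that the difference in shares was within counting error. Thinning left out 5 WT and 25 cKO-labelled cells. Unthinned, the shares were 0 of 61 (up to 4.92%) and 28 of 309 (9.06%, 6.11 to 12.8%). The exact binomial interval of the unthinned WT share ended at 5.87%, so the 2 intervals did not overlap. Thinned to 2000 UMIs, they overlapped. Thinned alike, 1 of 1327 WT and 0 of 1744 cKO-labelled microglia-like cells had a UMI (0.0754% and up to 0.172%), and 0 of 552 and 0 of 2187 oligodendrocyte-like cells did (up to 0.543% and 0.137%). Median depths before thinning were 4844 and 3753 UMIs in astrocyte-like cells, 6977 and 5835 in microglia-like cells, and 11777 and 8887 in oligodendrocyte-like cells of the WT and cKO-labelled libraries. In the cKO-labelled library 35 of the UMIs lay in 25 of the 184 cells of astrocyte cluster 7 and 3 UMIs in 3 of the 125 cells of astrocyte cluster 21. Mural-like cells, which line the outside of vessels, also held Dmp1, with 19 UMIs in 4 of 80 WT cells and 12 UMIs in 3 of 66 cKO-labelled cells. Ependymal-like cells had 6 and 3 UMIs (5.21 and 1.57 CPM), neuroblast-like cells 1 and 3 (0.437 and 1.93 CPM), neural stem or progenitor-like cells 0 and 2 (0 and 2.09 CPM), choroid plexus epithelial-like cells 0 and 2, endothelial-like cells 0 and 1, and fibroblast-like cells 1 and 0. Dmp1 (ENSMUSG00000029307) lies on chromosome 5 from 104202613 to 104214102 on the plus strand of GRCm38.

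The makeup of the recovered cells differed between the libraries. Astrocyte-like cells made up 0.841% of the WT cells kept (61 cells) and 3.16% of the cKO-labelled cells (309 cells), a difference of 2.32 percentage points (1.92 to 2.73). Endothelial-like cells made up 4.51% and 9.66%, a difference of 5.15 points (4.39 to 5.91). Choroid plexus epithelial-like cells went from 3.21% to 16.0%, oligodendrocyte-like cells from 7.61% to 22.5%, fibroblast-like cells from 0.855% to 3.90%, and neuron-like cells from 1.45% to 1.95%. Larger in the WT library were 3 immune classes: T or NK cell-like cells were at 9.50% and 3.47%, monocyte or dendritic cell-like cells at 7.42% and 2.24%, and neutrophil-like cells at 4.42% and 1.66%. Neuroblast-like cells were at 6.92% and 3.62%, neural stem or progenitor-like cells at 1.70% and 0.870%, border macrophage-like cells at 7.50% and 6.09% (-1.41 points, or -3.21 among named clusters only), and mural-like cells at 1.10% and 0.675%. The mural-like difference was within counting error at resolution 0.5 (-0.16 points, -0.42 to 0.09) and with doublets kept (-0.19, -0.45 to 0.06), and the neuron-like one with stricter cells (0.15, -0.24 to 0.52). The fibroblast-like cluster scored 0.680 for fibroblast and 0.454 for arachnoid barrier markers. With doublets kept, a cluster of 62 WT and 427 cKO-labelled barcodes that scored 0.660 and 0.471 for these lists was left unnamed. Shares of microglia-like (18.6% and 18.6%), B cell-like (1.74% and 1.76%) and ependymal-like cells (1.96% and 1.90%) differed by less than counting error when all cells kept are counted. At resolution 2 and with 50 principal components, where 46 WT barcodes leave the class, ependymal-like cells were at 1.32% and 1.90%, a difference of 0.58 points (0.20 to 0.96). With 50 principal components microglia-like cells differed by 2.22 points (1.08 to 3.35). Among cells of named clusters only, microglia-like cells made up 23.3% of the WT and 18.9% of the cKO-labelled cells, a difference of -4.35 points (-5.70 to -3.01). Ependymal-like cells then made up 2.46% and 1.94% (-0.52 points, -1.02 to -0.05), and the difference for neuron-like cells (0.17 points, -0.29 to 0.61) was within counting error. Unnamed clusters held 20.3% of the WT cells and 1.72% of the cKO-labelled cells. By cluster, in the WT and then the cKO-labelled library, cluster 8 held 13.7% and 0%, cluster 1 held 4.25% and 0.952%, cluster 17 held 1.53% and 0.338%, cluster 25 held 0.538% and 0.317%, and cluster 20 held 0.248% and 0.113%. Shares of recovered cells also depend on dissociation, and the difference for astrocyte-like cells was 0.654 points with stricter filters on cells and 3.92 points with no filter. With stricter filters a cluster of 27 WT and 88 cKO-labelled barcodes was left unnamed. It had Slc6a11, Slc1a2 and Ntsr2 among its leading genes, as astrocyte cluster 7 had. The value of 0.654 points is therefore not an effect of the filter alone.

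**Figure D1:**
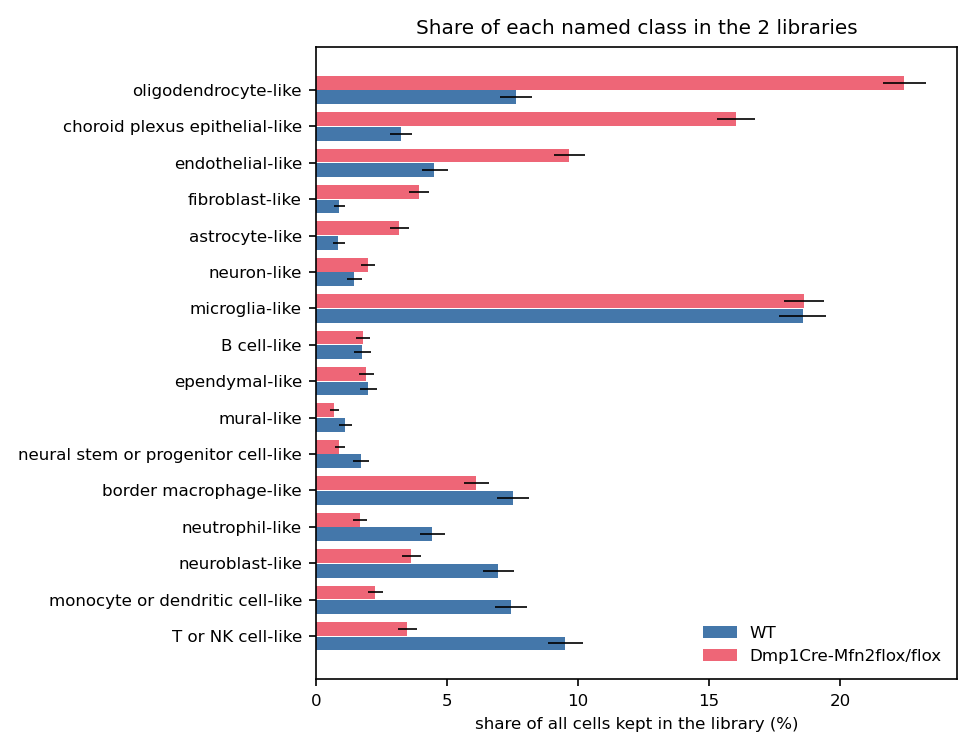
Share of all cells kept (%, horizontal axis) for each of the 16 compared classes in the WT and cKO-labelled (Dmp1Cre-Mfn2flox/flox) libraries, with exact binomial 95% intervals for counting error as bars. Oligodendrocyte-like cells went from 7.61% to 22.5% and choroid plexus epithelial-like cells from 3.21% to 16.0%, while microglia-like cells were at 18.6% in both.

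Transcripts encoded by the mitochondrial genome were higher in astrocyte-like cells of the cKO-labelled library. The list median log2 ratio over 13 genes was 0.70 (0.66 to 0.75), above 99.99% of random lists drawn from the genes nearest in level. These 13 genes make up the mitochondrial share of UMIs, so the percentile is no check apart from that share. In the list, 7 members were at least 1.5-fold higher. Among these were mt-Nd1 (log2 ratio 1.37) and mt-Nd2 (1.32), subunits of respiratory complex I, and mt-Co3 (1.21) of complex IV, while mt-Atp8 (-1.61) and mt-Nd4l (-0.83) were lower, and most of the 3' sequence of mt-Nd4l is also found in other genes. The nuclear genes of oxidative phosphorylation did not share this direction: 79 genes had a median of -0.11 (-0.19 to -0.06) at percentile 41.0 of random lists, with 1 member higher and 9 lower, and the sign of this median turned in some alternatives (0.06 at clustering resolution 0.5). The 21 measured genes of mitochondrial fusion and fission had a median of 0.10 (-0.13 to 0.33), with 4 higher and 1 lower. The 15 genes of mitochondrial transport and transfer had a median of 0.13 (-0.10 to 0.65). Gja1, the gap junction protein connexin 43, was higher among them (653 CPM in the WT and 1333 CPM in the cKO-labelled library, log2 ratio 1.03, interval 0.84 to 1.23), as was Rhot2, a GTPase that links mitochondria to motor proteins (1.38, interval -0.08 to 3.33). Mitophagy genes had a median of -0.23 (-0.48 to -0.10) over 18 genes, with 0 higher and 5 lower, among them the autophagy receptor Sqstm1 (-1.56), the kinase Ulk1 (-1.22) and Tomm7 (-1.11). Medians of the integrated stress response (0.36, -0.05 to 0.65), mitochondrial protein quality control (-0.08, -0.28 to 0.21, with a mean of 0.04), ER stress (-0.14, -0.27 to 0.17) and fatty acid oxidation (0.14, -0.05 to 0.38) had intervals that held 0. The cells came from clusters 7 and 21, which held 49.2% and 50.8% of the WT and 59.5% and 40.5% of the cKO-labelled astrocyte-like cells, and the median mitochondrial share of UMIs was 6.92% and 12.6% in cluster 7 and 3.30% and 6.69% in cluster 21.

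Genes of the astrocyte endfoot, the process that ensheathes brain vessels, were slightly higher in the cKO-labelled library (16 genes, median 0.31, interval 0.22 to 0.44, percentile 99.1, 3 higher and 0 lower). Gja1, the dystrophin gene Dmd (0.97) and the glutamate transporter Slc1a2 (0.66) were higher, and the water channel Aqp4 had a log2 ratio of 0.35. Secreted factors of astrocytes had a median of 0.50 (0.32 to 0.57) over 15 genes, with Ptn at 0.79 and Igfbp2 at 0.82. Cholesterol synthesis had a median of 0.29 (0.13 to 0.66) over 19 genes, with 8 higher and 0 lower, including the enzymes Dhcr7 (1.63), Msmo1 (1.45) and Sqle (1.28). The 10 measured genes of reactive astrocytes had a median of -1.37 (-1.67 to -1.10), with 1 higher and 6 lower. The intermediate filament gene Gfap was at 385 CPM (144 UMIs) in WT and 69.1 CPM (99 UMIs) in cKO-labelled cells, a log2 ratio of -2.48 (-2.86 to -2.10), and the class I gene H2-D1 was at 578 and 80.3 CPM. The Gfap difference lay in cluster 7, with 134 UMIs in 11 of 30 WT cells (1101 CPM) against 61 UMIs in 25 of 184 cKO-labelled cells (97.3 CPM). In cluster 21 Gfap was at 39.7 and 47.2 CPM. Oxidative defence had a median of -0.41 (-0.58 to -0.33) over 22 genes, with 1 higher and 8 lower, among them the metallothioneins Mt1 (-1.33) and Mt2 (-1.52). Glycolysis and lactate genes had a median of -0.19 (-0.34 to -0.08), hypoxia genes one of -0.19 (-0.40 to 0.26), heat shock genes one of -0.42 (-0.72 to -0.21) and glucocorticoid response genes one of -1.07 (-1.47 to -0.60). The endfoot median was 0.12 with 50 principal components of 3000 variable genes, which kept 19 WT and 98 cKO-labelled astrocyte-like cells, and the reactive median was then -0.38. In that setting the medians of cholesterol synthesis (-0.15) and heat shock (0.03) and the ratio of Gfap (0.11) turned to the other sign, and the median of glycolysis and lactate did so at resolution 0.5 (0.13).

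The naming rule admitted 1560 genes in astrocyte-like cells, of which the 10 with the largest ratios on each side are given. Lower in the cKO-labelled library were the phosphatase Dusp1 (650 against 66.4 CPM, 9.80-fold), the chemokine Ccl3 (733 against 75.4 CPM, 9.72-fold), the immediate early transcription factors Fos (9.20-fold), Jun (8.13-fold), Junb (6.57-fold) and Egr1 (5.97-fold), Cebpb (7.61-fold), H2-D1 (7.20-fold), Gfap (5.57-fold) and B2m (4.82-fold). In cluster 21, 570 UMIs of Fos lay in 11 of 31 WT cells and 168 in 43 of 125 cKO-labelled cells. There 165 UMIs of Ccl3 lay in 11 WT cells and 16 in 11 cKO-labelled cells. In cluster 7, Fos had 114 UMIs in 11 of 30 WT cells and 117 in 26 of 184 cKO-labelled cells, and Ccl3 had 109 in 7 and 92 in 16. Predicted doublets removed numbered 4 in the WT and 491 in the cKO-labelled library. Higher were Rnpc3, a component of the minor spliceosome (13.4 against 83.1 CPM, 6.21-fold), Vwa1 (4.04-fold), Gpr37 (3.98-fold), the lipase Abhd6 (3.88-fold), the manganese transporter Slc30a10 (3.68-fold), Tmem176a (3.36-fold), the non-coding RNA RF01962 (3.25-fold), the glypican Gpc5 (3.23-fold), Dhcr7 (3.11-fold) and Sorcs2 (3.08-fold). Gpr37 is also among the leading genes of oligodendrocyte clusters 12 and 13. The list of immediate early genes, which are also induced by tissue dissociation, had a median of -2.15 (-2.46 to -1.96), with 17 of 18 lower, and the list of inflammatory cytokines and NF-kB targets one of -2.64 (-2.90 to -2.26), with 15 of 16 lower. Transcripts of other cell types differed between the libraries in the same cells. Homeostatic microglia genes read in astrocyte-like cells had a median of -1.30 (-1.85 to -0.94), with 10 of 13 lower, myelin genes one of 0.81 (0.49 to 1.42), with 9 of 16 higher, and haemoglobin genes one of -2.04 (-2.12 to -1.97). The microglial median was 0.43 when doublets were kept.

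**Figure D2:**
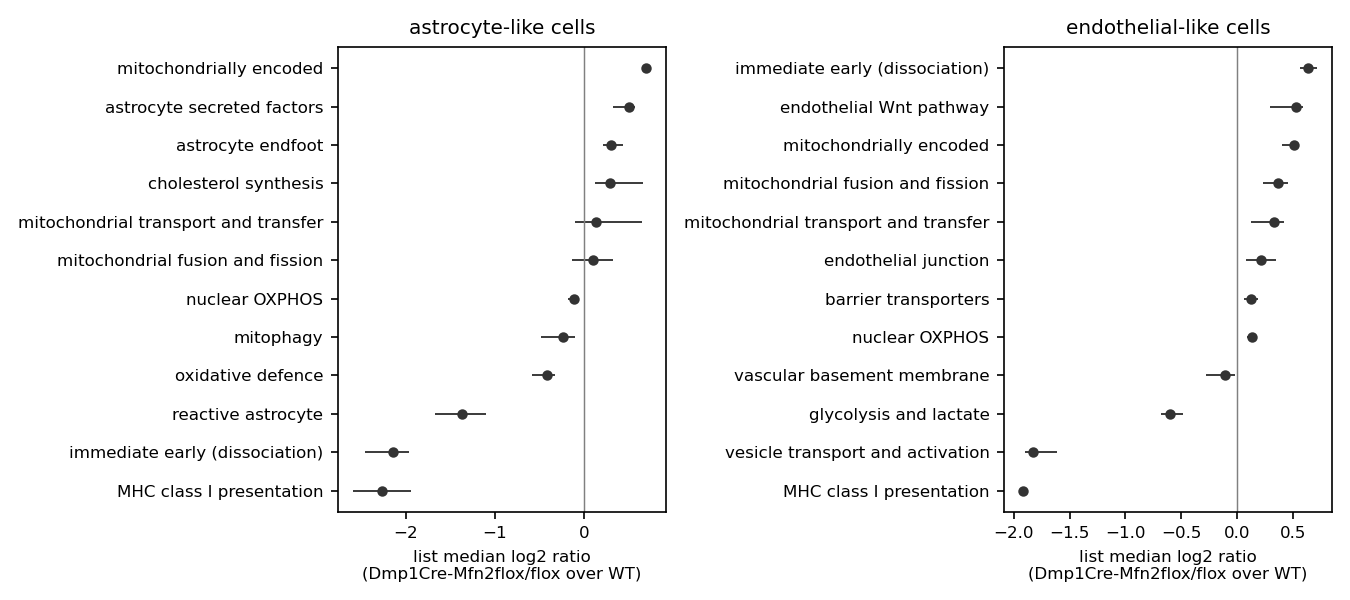
Median log2 ratio (cKO-labelled over WT, horizontal axis) of 12 gene lists in astrocyte-like cells and of 12 in endothelial-like cells; points are list medians and bars their 95% intervals for counting error. In astrocyte-like cells the mitochondrially encoded list lay at 0.70 and the immediate early list at -2.15; in endothelial-like cells these lay at 0.51 and 0.63, and the list of vesicle transport and activation at -1.83 over the class and at 0.16 within cluster 6 of resolution 2 (not drawn).

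Endothelial-like cells, which form the blood-brain barrier, had most of the measured barrier genes within 1.5-fold in the 2 libraries. The kinds of endothelial-like cells differed: at clustering resolution 2, a cluster with Vwf among its leading genes (cluster 17) held 59.3% of the WT and 2.44% of the cKO-labelled endothelial-like cells, one led by Gkn3 (cluster 7) held 8.39% and 45.4%, and cluster 6 held 32.3% and 52.2%. Only cluster 6, with 104 WT and 492 cKO-labelled cells, was large enough in both libraries to be compared by itself. The 19 endothelial junction genes had a median log2 ratio of 0.21 (0.08 to 0.35, percentile 84.5), with 3 higher and 1 lower. The tight junction gene Cldn5 was at -0.04 (-0.07 to -0.01), Ocln at 0.45 and Tjp1 at 0.52. Ctnnb1, which encodes beta-catenin, was higher (461 against 885 CPM, log2 ratio 0.94), as was Cgnl1 (0.68), and the connexin gene Gja4 was lower (-1.05). The 23 barrier transporters had a median of 0.13 (0.07 to 0.19), with 5 higher and 3 lower. Among the higher were the taurine transporter Slc6a6 (1.08) and the amino acid transporter Slc38a5 (1.03), and lower were the monocarboxylate transporter Slc16a1 (-1.07), Abcc4 (-0.81) and the transferrin receptor Tfrc (-0.80). The lipid transporter Mfsd2a was at -0.09 (-0.21 to 0.04). Genes of the Wnt pathway, which maintains the barrier, had a median of 0.53 (0.30 to 0.59, percentile 99.9) over 19 genes, with 8 higher and 1 lower, led by the receptor Fzd4 (1.28), with Spock2 at 0.89 and Sox7 at -0.97. Genes of vascular basement membrane had a median of -0.10 (-0.28 to -0.02) over 14 genes, with Nid2 at -1.19. The median over all 10869 genes measured in these cells was 0.15, so that the junction and transporter medians were close to that of all genes, and with median-of-ratios scaling the transporter median was 0.02. Within cluster 6 the medians were 0.09 (-0.07 to 0.20) for junctions and -0.05 (-0.17 to 0.00) for transporters. They were 0.14 (-0.04 to 0.26) for the Wnt pathway and -0.46 (-0.71 to -0.35) for basement membrane.

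Genes of vesicle transport and endothelial activation were lower over the class as a whole but not within cluster 6. Over the class their median was -1.83 (-1.90 to -1.61) over 16 genes, below all random lists, with 12 lower and 3 higher. The chemokine receptor Ackr1, a marker of venules, was at 362 CPM in the WT and 6.45 CPM in the cKO-labelled library, the fenestral diaphragm gene Plvap had a log2 ratio of -5.08, Lrg1 one of -3.95, and Angpt2, an antagonist of the receptor Tie2, one of -3.19. The caveolar genes Cavin2 (1.28), Cav2 (1.21) and Cav1 (0.98) were higher. MHC class I presentation genes were lower in all 12 members (median -1.91, -1.95 to -1.88), with H2-K1 at 3788 and 708 CPM and H2-Q7 at 735 and 18.9 CPM. Interferon response genes had a median of -0.48 (-0.60 to -0.34), with 12 of 24 lower and 2 higher, and the GTPase Iigp1 was at 1010 and 71.1 CPM. Inflammatory cytokines and NF-kB targets had a median of -2.51 (-2.74 to -2.36), with 16 of 18 lower, including Ptgs2, the inducible cyclooxygenase (597 against 79.3 CPM). Glycolysis and lactate genes had a median of -0.60 (-0.68 to -0.49) and hypoxia genes one of -0.45 (-0.61 to -0.33), with the vasodilator peptide Adm at -2.67. Immediate early genes went the other way, with a median of 0.63 (0.56 to 0.72) and 10 of 19 higher. Homeostatic microglia genes read in these cells had a median of -1.07 (-1.42 to -0.81), and astrocyte endfoot genes one of 0.65 (0.35 to 1.15). Within cluster 6 the median of vesicle transport and activation was 0.16 (0.03 to 0.32) over 14 genes, with Ackr1 at -0.52 (-1.46 to 0.48), that of inflammatory cytokines and NF-kB targets -0.16 (-0.28 to 0.09) and that of the interferon response 0.14 (-0.01 to 0.33). Medians there were -0.25 (-0.38 to 0.05) for glycolysis and lactate, -0.18 (-0.56 to 0.06) for hypoxia, 0.37 (0.29 to 0.47) for immediate early genes and, for transcripts of other cell types, 1.75 (1.31 to 2.20) for myelin genes, 1.38 (0.66 to 2.41) for astrocyte endfoot genes, 0.68 (0.21 to 1.16) for homeostatic microglia genes and -0.60 (-0.65 to -0.54) for haemoglobin genes. Class I presentation was lower within cluster 6 too (-1.62, -1.68 to -1.48).

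Among named genes of endothelial-like cells, whose ratios over the class include the different makeup of its clusters, the arterial gene Gkn3 was higher in the cKO-labelled library (6.59 against 130 CPM, 19.7-fold), as were the clock-controlled transcription factor Hlf (9.95-fold), alkaline phosphatase Alpl (9.38-fold), Cthrc1 (6.12-fold), Lmo7 (5.22-fold), Ptprr (29.5 against 147 CPM), endothelin 3 Edn3 (4.89-fold), Slc26a10 (4.74-fold), Tril (4.72-fold) and Pomc (4.49-fold). Lower were the T cell chemokines Cxcl10 (585 against 10.7 CPM, 54.5-fold) and Cxcl9, with 357 UMIs against 2 (log2 ratio -8.33, -11.38 to -6.47), the invariant chain Cd74 (2517 against 39.1 CPM, 64.4-fold), the class II and class I genes H2-DMb1 (75.1-fold) and H2-Q6 (62.2-fold), Ackr1 (56.1-fold) and the protease inhibitor Serpina3f (153-fold). Serpina3n had 155 UMIs against 2 (log2 ratio -7.13, -10.19 to -5.25). Ms4a4d had 230 UMIs and the ubiquitin-like modifier Ubd 202 UMIs in the WT library and 0 in the cKO-labelled library, at least 138-fold and at least 121-fold lower against a floor of 3 counts over the class. Within cluster 6 Gkn3 had 0 and 19 UMIs, Cxcl9 1 and 0, Ms4a4d 7 and 0, Ubd 0 and 0 and Serpina3n 2 and 1 (log2 ratio -2.52, -8.41 to 1.74), and Cthrc1 had a log2 ratio of 1.25 and Lmo7 one of 1.15. Slc26a10 had one there of -0.90 (-2.07 to 0.34), opposite in sign to that over the class, Cxcl10 one of -1.52 (-2.14 to -0.91) and Cd74 one of -6.68 (-7.82 to -5.73). Serpina3f was at -4.19 (-6.59 to -2.42) within cluster 6, H2-DMb1 at -4.61 (-7.77 to -2.54) and Alpl at 1.87 (0.41 to 3.81). Mitochondrial lists in these cells were at 0.51 (0.40 to 0.53) for the 13 mitochondrially encoded genes, with 3 higher and 2 lower, and at 0.13 (0.09 to 0.17) for the 79 nuclear genes of oxidative phosphorylation, with 2 higher and 2 lower. Mitochondrial fusion and fission was at 0.36 (0.23 to 0.46), with Oma1 (0.96), Immt (0.76), Mfn2 (0.74) and Afg3l2 (0.68) higher and none of the 20 members lower, and mitochondrial transport and transfer at 0.33 (0.13 to 0.42). Within cluster 6 these 4 lists were at 0.64 (0.56 to 0.67), 0.22 (0.15 to 0.28), 0.38 (0.13 to 0.51) and 0.23 (-0.03 to 0.45).

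In microglia-like cells homeostatic genes were higher in the cKO-labelled library (15 genes, median 0.63, 0.61 to 0.67, percentile 99.99, 9 higher and 1 lower). The purinergic receptor P2ry12 was at 803 and 1865 CPM (log2 ratio 1.22), and the transcription factor Sall1 (1.60), Gpr34 (1.25) and the fractalkine receptor Cx3cr1 (1.00) were higher, while the hexose transporter Slc2a5 was lower (-4.35). The median over all genes in these cells was 0.13. Genes of disease-associated microglia were lower (20 genes, median -0.72, -0.77 to -0.55, 1 higher and 11 lower), among them apolipoprotein E, Apoe (6546 against 1316 CPM), the receptor Axl (-2.50) and galectin 3, Lgals3 (-1.86). The interferon response had 18 of 24 members lower and 0 higher (median -0.94), MHC class I presentation 8 of 12 lower (-0.83), and inflammatory cytokines and NF-kB targets 8 lower and 4 higher (-0.40), with the monocyte chemokines Ccl7 at -4.23 and Ccl2 at -1.87 and Nfkbiz at 1.34. Immediate early genes were higher (median 1.02, 0.96 to 1.06, 12 of 19 higher), and Egr1 (6.15-fold), Fos (6.14-fold), the linker histone H1f0 (5.84-fold), Jun (5.67-fold) and Btg2 (5.37-fold) led the named genes. Named as lower were the acute-phase gene Saa3, with 1107 UMIs in the WT library and 1 in the cKO-labelled library (log2 ratio -10.28, -15.59 to -7.80), the complement gene C4b (53.3-fold), Slc2a5 (20.4-fold), Acp5 (16.8-fold) and Hcar2 (16.7-fold). Different clusters held most of this class: cluster 3, led by Gpr84 and the cytokine Il1a beside microglial markers, held 78.2% of the WT and 4.95% of the cKO-labelled microglia-like cells, and cluster 24 held 12.8% and 67.1%. At resolution 2, clusters 18, 19, 34 and 35 each held at least 50 microglia-like cells of both libraries, and several lists did not differ within them as over the class. In this order of clusters, disease-associated genes had medians of 0.46, 0.08, -0.12 and 0.03. Inflammatory cytokines and NF-kB targets had 0.21, 0.10, 0.65 and 0.26, and the interferon response 0.35, 0.02, -0.71 and -0.63. Homeostatic genes had 0.26, 0.35, 0.04 and 0.49, immediate early genes 0.72, 0.33, 1.12 and 0.38, and class I presentation -0.51, -0.37, -0.81 and -0.88. Jun was at 0.08 in cluster 35, and Saa3 had at most 1 UMI per library in clusters 19, 34 and 35. Acp5 was at -5.10 (-10.40 to -2.61) in cluster 18 and -1.04 (-2.22 to 0.31) in cluster 19. It had 0 and 1 UMIs in cluster 34 and 0 and 12 in cluster 35. H1f0 was at 0.87 (-0.10 to 2.04) in cluster 34, and at 2.45, 2.11 and 3.16 in clusters 18, 19 and 35. Myelin genes read in microglia-like cells had a median of 1.01 (0.83 to 1.20), with 13 of 17 higher.

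Class I presentation genes were lower in the cKO-labelled library in all 16 compared classes, with medians from -3.31 in neuroblast-like to -0.65 in T or NK cell-like cells. Free RNA in the WT droplets would carry at most 14.4% of the WT excess in class I CPM in endothelial-like and 3.87% in microglia-like cells, but 113% in astrocyte-like, 58.1% in oligodendrocyte-like, 159% in neuron-like and 45.4% in neuroblast-like cells. Haemoglobin genes, which mark red cells or their free RNA, also had a median below 0 in all 16 classes, from -6.22 in ependymal-like to -0.29 in endothelial-like cells. At resolution 2, where the 46 WT barcodes, with haemoglobin genes among the leading ones of their cluster, leave the class, the ependymal-like median was -4.79 (-5.07 to -4.57). Class I there was at -1.29 (-1.69 to -1.09) instead of -1.81. In border macrophage-like cells the haemoglobin median was 0.59 (0.49 to 0.68) within cluster 12 of resolution 2, against -1.53 over the class. Mural-like class I was at -1.98 (-2.37 to -1.57) at resolution 0.5, against -2.93. Interferon response genes had medians below 0 in all 16 classes (-2.67 to -0.08), but not in every setting. Within clusters of resolution 2 these medians were 0.14 in endothelial cluster 6 and 0.35, 0.02, -0.71 and -0.63 in microglia clusters 18, 19, 34 and 35. The sign of the astrocyte-like one turned under the free-RNA rule. Mitochondrially encoded genes had a median above 0 in 12 classes and below 0 in 4 (-0.25 to 0.75), nuclear genes of oxidative phosphorylation one above 0 in 6 and below 0 in 10 (-0.33 to 0.47), and immediate early genes one above 0 in 8 and below 0 in 8 (-2.15 to 1.19). Oligodendrocyte-like cells had a median of 0.00 (-0.01 to 0.01) over 17 myelin genes, with Opalin at 0.85 and Mbp, myelin basic protein, at -0.43, and their class I genes were lower in 12 of 12 members (median -2.13). The named genes of this class were Jph4 (2.56-fold), Prima1 (2.48-fold) and Srgap1 (2.48-fold), higher, and the stress gene Gadd45b (5.69-fold), the signalling inhibitor Spry2 (4.69-fold) and Gstp1 (4.55-fold), lower; most of the 3' sequence of Gstp1 is also found in other genes. Within it cluster 13 held the largest part of the WT cells (41.7%) and cluster 12 of the cKO-labelled cells (52.1%). The median over all genes also lay further than 0.1 from 0 in neutrophil-like (0.29), T or NK cell-like (-0.18) and B cell-like cells (-0.12).

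**Figure D3:**
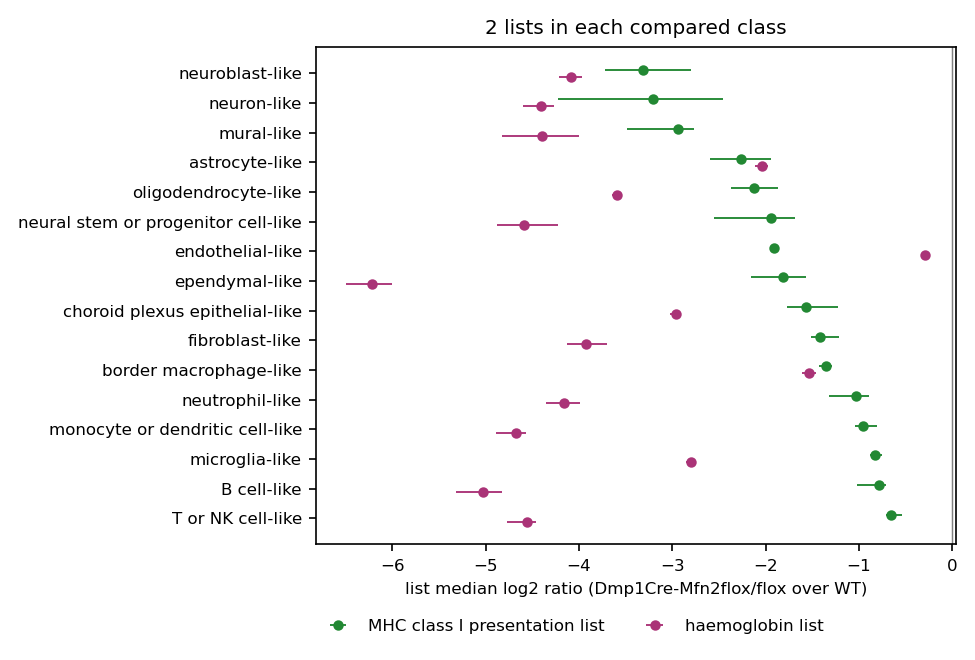
Median log2 ratio (cKO-labelled over WT, horizontal axis) of the MHC class I presentation list and the haemoglobin list in each of the 16 compared classes, with 95% intervals for counting error as bars. All medians lie below 0, from -3.31 to -0.65 for class I presentation and from -6.22 to -0.29 for haemoglobin; the ependymal-like haemoglobin median was -4.79 at resolution 2 (not drawn).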

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

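The test of pairs of cells was chosen only after the result was seen. A cluster of 995 WT barcodes and 0 cKO-labelled barcodes (which allows a share of up to 0.0307%) was used in no comparison of gene levels but counts among all cells kept in the shares (without unnamed clusters the microglia-like share differed by -4.35 points), and stands out because it holds 13.7% of the WT cells kept and has no counterpart in the other library. Its profile lay close to that of the whole WT library (correlation 0.967), with a median of 4431 UMIs. Free RNA spread evenly over all droplets is argued against, since it came to at most 15.6% of the cluster's median UMI count in 5 named classes, and so are pairs of cells, since 96.8% of the barcodes (963 of 995, 95.5 to 97.8%) held markers of at least 4 of 5 lineages against 0.101% of random pairs. Contents of many cells pooled in merged droplets or a lysed clump remain a candidate explanation: 23 of 24 marker lists were at 50% or more of their level in the whole library, but the spread between barcodes (median dispersion index 1.55, against 132 in pairs) left it open, and no biological explanation was tested.

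Immediate early genes stood out because they went opposite ways in 2 classes, with a list median log2 ratio of -2.15 in astrocyte-like cells and 1.02 in microglia-like cells. The difference between the classes was not tested. The astrocyte-like value rests on few WT cells. Fos had 570 UMIs in 11 of 31 WT and 168 in 43 of 125 cKO-labelled cells of cluster 21. In cluster 7 it had 114 in 11 of 30 and 117 in 26 of 184. The doublet caller marked only 4 WT barcodes, and whether doublets carried these UMIs was not tested.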

How the results depend on the processing

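A common doublet threshold, shares of named clusters only, the free-RNA rule and the removal of transcript length and GC content were chosen only after the results were seen. No paired analysis was possible because both libraries carry the replicate number 1 only. Each group is 1 library, so the intervals leave out differences between mice and preparations, and depth limits scarce genes such as Mfn2 and Dmp1. Intervals of ratios and list medians also leave out the spread of UMIs between cells. Gfap, for example, had 134 UMIs in 11 WT cells of astrocyte cluster 7. Across alternatives, 141 values of the main results stayed within their counting interval, 58 moved beyond it and 3 whose interval excluded 0 changed sign; for other genes, lists and shares the counts were 2335, 405 and 13. Sign changes of values whose interval held 0 are not in these counts of 3 and 13, as for Mfn2 in astrocyte-like cells when cells are weighted equally. Elane, Ctsg and Mpo in ependymal-like cells are left out of these counts at resolution 2 and with 50 principal components, since no library exceeded the floor of 3 counts there. In both settings Mpo had 3 and 1 UMIs, a log2 ratio of -2.51 (-8.22 to 1.13), and Elane and Ctsg had 0 and 0. The endothelial junction median stayed between 0.11 and 0.24 in 15 settings, the mitochondrially encoded median in endothelial-like cells between 0.41 and 0.51 in 15, and the Mfn2 ratio in endothelial-like cells between 0.47 and 1.23 in 12.

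With stricter cells, 6689 WT and 8488 cKO-labelled cells passed, the share differences were 0.654 (astrocyte-like) and 6.17 points (endothelial-like), Mfn2 in astrocyte-like cells was at 2.07, and their medians were 0.21 (endfoot), 0.54 (mitochondrially encoded), -0.0213 (nuclear OXPHOS) and -0.41 (reactive). Signs turned for Gfap in astrocyte-like (0.00165), Egr3 in monocyte or dendritic cell-like (-0.95) and Jchain in B cell-like cells (-0.14). With 50 principal components of 3000 variable genes, the astrocyte-like share difference was 0.741, Mfn2 there was at 2.77, and medians were 0.12 (endfoot), 0.63 (mitochondrially encoded) and -0.38 (reactive). Signs turned for nuclear OXPHOS (0.00874), cholesterol synthesis (-0.15), heat shock (0.0286), homeostatic microglia genes (0.11) and Gfap (0.11) in astrocyte-like cells and Mag in neuron-like cells (-0.56). These 2 settings kept 24 WT and 86 cKO-labelled, and 19 and 98, astrocyte-like cells. With stricter cells the only astrocyte-like cluster shared leading genes with cluster 21, where Gfap was at 39.7 and 47.2 CPM. A cluster of 27 WT and 88 cKO-labelled barcodes with leading genes of astrocyte cluster 7 was left unnamed. A cluster of 158 WT and 86 cKO-labelled barcodes that shared Cd209a and Ccl17 with monocyte or dendritic cell-like cluster 18 was named mast cell. Monocyte or dendritic cell-like were then 348 WT and 115 cKO-labelled cells, against 538 and 219.

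With no cell filter, 7746 and 10544 cells passed, the astrocyte-like share difference was 3.92, and medians were 0.22 (endfoot), 0.93 (mitochondrially encoded), -0.24 (nuclear OXPHOS) and -0.94 (reactive). With doublets kept, 10263 cKO-labelled cells passed, medians were 0.14 (endfoot), 0.63 (mitochondrially encoded), -0.23 (nuclear OXPHOS) and -0.69 (reactive), and homeostatic microglia genes in astrocyte-like cells turned to 0.43. A common doublet threshold left 6907 WT cells. At resolution 0.5, medians were 0.81 (endfoot), 0.63 (mitochondrially encoded), -1.72 (reactive) and 0.20 (barrier transporters), and in astrocyte-like cells nuclear OXPHOS (0.0644) and glycolysis and lactate (0.13) changed sign. Among named clusters only, the endothelial-like share difference was 4.18.

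With TMM factors and then median-of-ratios factors, barrier transporters were at 0.0376 and 0.0242, nuclear OXPHOS in endothelial-like cells at 0.0415 and 0.0280, homeostatic microglia at 0.54 and 0.55, and vesicle transport and activation at -1.92 and -1.93; with TMM nuclear OXPHOS in astrocyte-like cells was at -0.0579. With cells weighted equally, Mfn2 in astrocyte-like cells was at -0.69, medians were 0.12 (endfoot), 0.51 (mitochondrially encoded, astrocyte-like), 0.61 (homeostatic microglia) and -1.997 (vesicle transport and activation), and Mag in neuron-like cells turned to -0.13. Totals without mitochondrial, ribosomal protein and haemoglobin genes gave 0.59 for homeostatic microglia. With transcript length and GC content removed, medians were 0.19 (endfoot), 0.19 (barrier transporters), 0.86 (homeostatic microglia) and 0.81 (mitochondrially encoded, astrocyte-like), and nuclear OXPHOS was at 0.22 in endothelial-like cells and turned to 0.0624 in astrocyte-like cells. Under the free-RNA rule the reactive median was -0.74, and homeostatic microglia (0.20) and interferon response genes (0.11) in astrocyte-like cells changed sign. List filters of 1 and 100 UMIs gave reactive medians of -2.26 and -2.24, and the filter of 100 a vesicle transport and activation median of -1.53. The share of cKO-labelled astrocyte-like cells with Dmp1 was 5.79% thinned to 2000 UMIs and 9.06% unthinned. Some settings also changed which barcodes a class held, as given for stricter cells. Beyond that and the numbers of cells that each filter keeps by construction, the causes of these differences were not tested.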

Other observations

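The splits of the free-RNA test by class and both comparisons with genotype were chosen only after the results were seen. Phagocytes of 3 classes shared a higher level of Cybb, the catalytic subunit of the phagocyte NADPH oxidase, in the cKO-labelled library: 32.7 against 546 CPM in border macrophage-like cells (16.7-fold), 88.6 against 1028 CPM in monocyte or dendritic cell-like cells (11.6-fold) and 55.2 against 1150 CPM in neutrophil-like cells (20.8-fold). Beside it, Hist1h1c (10.9-fold) and Cyr61 (9.36-fold) were higher in border macrophage-like cells, Egr3 (8.70-fold, but log2 ratio -0.95 with stricter cells) in monocyte or dendritic cell-like cells, and Ptgds (4.82-fold) and Nktr (4.23-fold) in neutrophil-like cells. Ptgds is in the fixed marker list of arachnoid barrier cells, and whether free RNA carried it in neutrophil-like cells was not tested. Among monocyte or dendritic cell-like cells, Retnla was read only in cKO-labelled ones (0 against 118 UMIs, at least 129-fold higher), all in cluster 28 of resolution 2, while Egr3 was at -0.78 (-2.48 to 0.57) within cluster 30. Lower were Saa3 (95.2-fold), Serpina3f (52.2-fold) and Cxcl9 (1050 UMIs against 1, log2 ratio -9.87, -15.18 to -7.39) in border macrophage-like cells. At resolution 2, cluster 24 held 76.2% of the WT and 13.1% of the cKO-labelled border macrophage-like cells, and cluster 9 held 12.7% and 76.5%. Within clusters 9, 12 and 24 the log2 ratio of Cybb was 5.51, 4.002 and 4.12. That of Hist1h1c was 3.15, 3.21 and 2.24 and that of Cyr61 1.97, 0.62 (-1.50 to 2.74) and 1.97. In cluster 9 Saa3 had 1 and 6 UMIs and Serpina3f 3 and 0, and in cluster 24 Cxcl9 was at -3.07 (-3.81 to -2.42) and Serpina3f at -2.83. Saa3 had 494 and 0 UMIs in cluster 12 and 147 and 0 in cluster 24. In monocyte or dendritic cell-like cells Saa3 (82.1-fold), Rhov (20.7-fold) and AW112010 (17.6-fold) were lower, and in neutrophil-like cells Gbp2 (40.3-fold), Stfa1 (28.7-fold) and H2-Q7 (27.6-fold). B cell-like cells held different immunoglobulin heavy chains: Ighg2c had 7783 UMIs in the WT library and 0 in the other (at least 2691-fold lower), and Igha 0 and 4114 (at least 1322-fold higher). Jchain (11.2-fold, but log2 ratio -0.14 with stricter cells) and Cd55 (5.62-fold) were higher there, and Slpi (45.6-fold) and Fabp7 (170 UMIs against 1, log2 ratio -7.46, -12.77 to -4.96) lower. With stricter cells Igha was no longer among the 10 leading genes of a B cell-like cluster, while Ighg2c was. The number of cells that held the UMIs of these chains was not counted. In T or NK cell-like cells the NK receptor genes Klri2 (10.9-fold) and Klra8 (9.27-fold) and Rflnb (9.20-fold) were higher, and Hist1h2ap (34.6-fold), the proliferation gene Mki67 (21.7-fold) and AA467197 (17.3-fold) lower. The makeup of this class differed: cluster 0, led by NK genes, held 7.98% of its WT and 39.8% of its cKO-labelled cells, and cluster 14 held 43 WT cells and 1 cKO-labelled cell. Within cluster 0 of resolution 2, Klri2 was at 1.78, Klra8 at 1.33, Rflnb at 0.66 (-3.61 to 6.54), Hist1h2ap at -1.15 (-3.37 to 0.83) and Mki67 at -4.43. Within cluster 3, Rflnb was at 3.27 (1.96 to 4.62), Hist1h2ap at -3.41 (-8.74 to -0.89) and Mki67 at -2.34 (-5.41 to -0.44). Klri2 had 5 and 0 UMIs and Klra8 3 and 0 in cluster 3.

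In neuron-like cells the neuropeptide genes Calca (1031 UMIs against 2, log2 ratio -9.60, -12.65 to -7.75) and Tac1 (469 against 2, -8.47, -11.52 to -6.61) and the synuclein gene Sncg (462 against 1, -9.45, -14.75 to -6.96) were lower in the cKO-labelled library. Transcripts of oligodendrocytes were higher there: Opalin (0 against 186 UMIs, at least 41.1-fold), Olig1 (21.2-fold) and Mag (11.5-fold; log2 ratio -0.13 with cells weighted equally and -0.56 with 50 principal components). At resolution 2 Calca, Tac1 and Sncg had 0 UMIs in neuron cluster 41, where Mag was at -1.36 (-2.27 to -0.46), Olig1 at -0.62 (-2.49 to 1.38) and Opalin had 0 and 4 UMIs, so that these differences lay in cluster 43 alone. Npy had 840 UMIs in WT neural stem or progenitor-like cells and 0 in the other library (at least 167-fold lower), Frzb had 143 against 1 (log2 ratio -6.41, -11.72 to -3.91) and Cxcl10 was 41.4-fold lower, while Cyr61 (8.45-fold), Draxin (7.36-fold) and Txnip (5.22-fold) were higher. Npy and Frzb are in the fixed marker list of olfactory ensheathing cells. With 50 principal components, 18 WT and 1 cKO-labelled cells formed an olfactory ensheathing-like class. Neural stem or progenitor-like cells then numbered 98 and 66, against 123 and 85. Whether cells of that other class carried Npy and Frzb was not tested. Neuroblast-like cells had higher linker histone genes (Hist1h1b, 17.0-fold; Hist1h1e, 9.18-fold; Hist1h1c, 7.89-fold) and lower Ucp2 (14.2-fold), Neat1 (7.92-fold) and Evi2a (6.63-fold). In mural-like cells the contractile genes Tpm2 (4.87-fold), Acta2 (3.87-fold) and Tagln (3.63-fold) were higher, and Cd74 (1548 UMIs against 3, log2 ratio -7.21, -9.49 to -5.66), H2-Q6 (264 against 1, -6.24, -11.55 to -3.75) and Scgb3a1 (240 against 1, -6.10, -11.41 to -3.61) lower. At resolution 0.5, 56 rather than 80 WT barcodes were mural-like and 351 rather than 327 endothelial-like. There H2-Q6 had 11 and 0 UMIs and Scgb3a1 0 and 0, while Cd74 was at -7.06 and Tpm2, Acta2 and Tagln at 1.20, 0.85 and 0.79. Choroid plexus epithelial-like cells held the imprinted gene Dlk1 in the cKO-labelled library (0 against 868 UMIs, at least 36.9-fold higher), with Hspa1b (6.67-fold; log2 ratios of -0.98 and -0.55 within clusters 31 and 32 of resolution 2) and Kcnq1ot1 (3.61-fold; 0 against 12 and 2 against 12 UMIs there) higher and Gstp1 (7.54-fold) and Fbxo44 (3.36-fold) lower. In ependymal-like cells the clock-controlled genes Dbp (9.01-fold) and Hlf (4.70-fold) and Dusp1 (3.91-fold) were higher, and the granule protease genes Elane (202 against 0 UMIs, at least 111-fold) and Ctsg (194 against 0, at least 107-fold) and the peroxidase gene Mpo (250 against 1, log2 ratio -8.69, -14.00 to -6.20) lower. At resolution 2 the last 3 had at most 3 UMIs in the ependymal-like cells of each library, and an unnamed cluster of 46 WT and 0 cKO-labelled barcodes (median 961.5 UMIs) was led by Mpo, Ctsg and Elane, while 96 WT barcodes rather than 142 were ependymal-like. In fibroblast-like cells Unc5c (10.2-fold), Dbp (8.68-fold) and Stbd1 (6.26-fold) were higher and Cxcl10 (19.2-fold), Iigp1 (15.9-fold) and H19 (9.22-fold) lower.

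Lower class I presentation genes in the cKO-labelled library may have more than 1 source. Free RNA of immune cells in the WT library is argued against in endothelial-like and microglia-like cells, where it would carry at most 14.4% and 3.87% of the WT excess. It stays open in astrocyte-like (113%), oligodendrocyte-like (58.1%), neuron-like (159%) and neuroblast-like cells (45.4%). A response in 1 of the 3 pooled WT brains was left open, although 80.5% of WT endothelial-like cells (236 of 293, 75.5 to 84.9%) lay above the other library's 95th percentile of class I UMIs. With 1 library per genotype, the genotype cannot be told apart from any other difference between the pools.

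A set of 16 genes, 14 lower and 2 higher in the cKO-labelled library, had a median log2 ratio of at least 1 in size with an SD of at most 0.5 over the classes that measured them, out of 3872 genes measured in at least 8 classes; single classes still varied, Rpl5 from -0.39 to 1.93 and Rps28 from -1.96 to 0.03. Transcript length and GC content are argued against as the whole cause, since removing their trend kept 92.0% of the median size of the log2 ratios. Reads shared with near-identical genes are a candidate explanation for 7 of the 16 (43.8%, 19.8 to 70.1%), among them Gm10076, Gstp1, Rpl35, mt-Nd4l, Nme2 and Rpl5, against 3.09% of 3853 other genes. For the other genes of the set, mt-Atp8 and Slc39a1 among them, no test found a source. With 1 library per genotype, the genotype cannot be told apart here either.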
